A study of Mus musculus with 8 samples.

How the data were processed

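The series holds 8 RNA-seq libraries of 4T1 spheroids. 4T1 is a transplantable mouse mammary carcinoma line from a BALB/c mouse, often used as a model of triple-negative breast cancer. Per the labels' protocols, the cells carried a lentivirus for a scrambled short hairpin RNA (shCtrl, 4 libraries) or for a hairpin against Tlr7 (shTlr7, 4 libraries), and were cultured as hanging-drop spheroids. RNA was isolated with a Norgen total RNA kit, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

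The authors deposited 1 table of whole-number read counts per gene, with 1 column per library and no normalization. The submitters' processing notes name STAR 2.7.5, DESeq2 1.32.0 and the mouse build GRCm38, without their roles. The counting program, its strand setting and the annotation are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner cannot be told apart. The deposited counts have 41730 rows, of which 39351 carry a symbol of the RefSeq annotation of GRCm38.p6 and 2379 carry such a symbol with a suffix that marks a further copy of the gene. There are 1766 genes with such a copy. Of the 1729 that also have a row of their own, 1331 have under 10 counts in that row over all 8 libraries, as would happen where reads that fit both copies were discarded. Tap1, chosen after its values were seen, is such a gene, and fold changes of genes with copies are uncertain. Copies were recognised by this suffix only. Genes of a family with symbols of their own, such as Prl2c3, Ifit3b and Ifnl2, were not screened for shared sequence. The same uncertainty may therefore apply to them. None of the 13 mitochondrial protein-coding genes has a row. In all, 16870 rows are 0 in every library.

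Library totals were 19.2, 51.5, 20.3 and 23.4 M counts for shCtrl replicates 1 to 4, and 18.1, 93.8, 34.0 and 28.4 M for shTlr7 replicates 1 to 4. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr on the groups, which left 13393 genes, and scaled by TMM. The comparison of shTlr7 with shCtrl used edgeR's quasi-likelihood test (robust glmQLFit, glmQLFTest) with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values were computed here from the deposited counts with TMM-scaled library sizes. Values are given as mean ± SD over 4 libraries per group.

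For this comparison, 38 gene lists were fixed before the data were examined. Lists with at least 5 tested members (34 lists) were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it stood camera with an estimated correlation, fry, Fisher's exact test on called members, and counts adjusted over the list alone. Libraries were also described by principal components of the 1000 most variable genes and by Spearman correlation.

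Genes are named by a rule fixed before the data were examined. It takes Tlr7, the 12 largest rises and 12 largest falls among genes past the threshold with an average log2 CPM of at least 1 and all 4 libraries of one group above all 4 of the other in CPM, the 5 rising and 5 falling genes with the lowest p under the same conditions, and per list the 4 tested members with the lowest p. Predicted or unnamed genes (Gm numbers, names ending in Rik or -ps with or without a number, clone names and identifiers without a symbol) are left out of the first parts. Some genes that the rule takes are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

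The test was tried on simulated data with the real means, dispersions and library sizes, over 13393 genes of the same comparison. It recovered 34% of the 50 genes with the smallest simulated change, which was under 1.5-fold, 78% of 50 changed 1.5-fold, 98% of 50 changed 2-fold and 98% of 50 changed 3-fold, and 3.95% of 177 calls were unchanged genes. Few of the simulated genes were changed, while 7517 were called in the real data, so these shares may not carry over to the real comparison. No pair of libraries within a group agreed within sampling noise. The chi-square per degree of freedom between pairs ranged from 2.35 to 24.1.

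Alternatives fixed before the data were examined were RLE and upper-quartile scaling, library size only, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a minimum of 1 CPM in 4 libraries, adjusted p under 0.01, a glmTreat fold of 1.5, the replicate number as a block, and leaving out each library. Alternatives added after seeing the data summed the copies of a gene, thinned all libraries to the smallest total of 18.1 M, left out both libraries numbered 4, and removed each library's trend over transcript GC content and length (GENCODE M21, known for 12527 of the 13393 genes). Three-prime UTR sequences came from the same annotation, and the exon overlap between genes was computed with bedtools 2.31.1. Intervals and floors of low counts cover counting error only.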

Results

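Gene expression was measured by RNA-seq in spheroids of 4T1 mouse mammary carcinoma cells that expressed a scrambled hairpin RNA (shCtrl, n = 4) or a hairpin against Tlr7 (shTlr7, n = 4). Tlr7 encodes an endosomal receptor for single-stranded RNA. The only comparison of the design asks which transcripts differ in these cancer cells once Tlr7 is targeted. Total counts ranged from 18.1 to 93.8 M per library. The biological coefficient of variation between libraries of a group was 6.76%. The labels do not say that the 4 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

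Libraries fell apart by group. The first principal component of the 1000 most variable genes held 85.6% of the variance and separated the 4 shCtrl from the 4 shTlr7 libraries. Spearman's rho between libraries, across genes, lay between 0.995 and 0.999 within groups and between 0.977 and 0.982 across groups. The second component held 4.85% of the variance and set the library numbered 4 of each group apart from the rest.

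**Figure D1:**
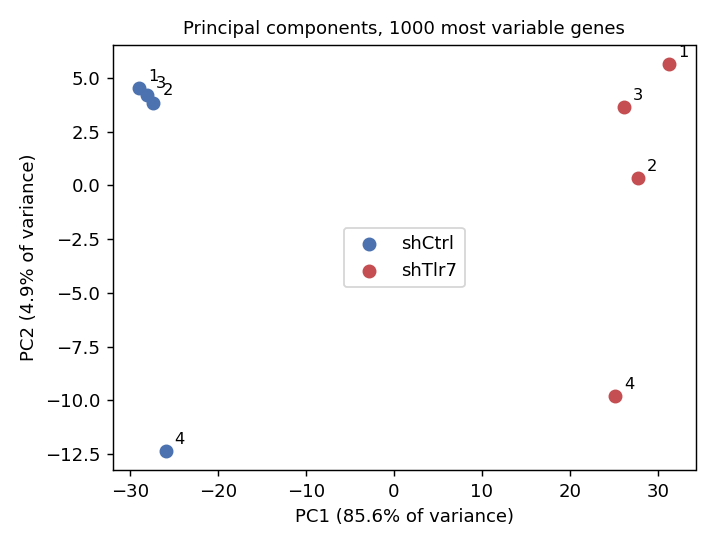
Principal components of log2 CPM over the 1000 most variable genes, 1 point per library, labelled with its replicate number and coloured by group. The first axis (85.6% of variance) parts shCtrl from shTlr7, and the second (4.85%) puts both libraries numbered 4 below the others.

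Tlr7 itself was close to absent from all 8 libraries. The gene (chromosome X, 167303380 to 167330574, GRCm38.p6) had 2, 3, 2 and 2 counts in shCtrl replicates 1 to 4, and 0, 4, 3 and 0 counts in shTlr7 replicates 1 to 4. The 0 counts allow up to 0.166 CPM in shTlr7 replicate 1 and 0.106 CPM in shTlr7 replicate 4, taking 3 counts over the library total without TMM scaling as the limit. Pooled over each group, 9 counts in shCtrl stood against 7 in shTlr7, a ratio of 0.475 with an exact 95% interval from 0.15 to 1.43 (exact binomial test, two-sided p = 0.196, counting error only). Tlr7 did not pass the filter on low counts. Without that filter its log2 fold change was -1.02 ± 0.79 (SE), with an edgeR adjusted p of 0.339. Among the alternatives only limma-voom put Tlr7 past the threshold, at -1.49 (limma adjusted p = 0.0438). With thinned libraries the log2 fold change was -1.86 (edgeR adjusted p = 0.172). A lower level of Tlr7 RNA in shTlr7 was therefore not detectable at this depth by the edgeR test.

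Expression differed broadly between the groups. Transcripts of the extracellular matrix and of cell adhesion fell as groups, and interferon-stimulated transcripts rose (camera adjusted p = 5.09e-16 for the rise, and adjusted p = 0.367 with an estimated correlation). Of 13393 genes tested, 3927 were higher and 3590 lower in shTlr7 (edgeR quasi-likelihood test, adjusted p under 0.05). At least a 2-fold change was found for 441 of the higher and 566 of the lower genes, while 2314 of the called genes differed by under 1.2-fold. The groups did not overlap in CPM for 49.8% of genes, where chance gives 2.86%. Scaling by library size alone moved the median log2 fold change up by 0.104 and changed the split to 5513 higher and 2491 lower genes.

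The largest falls included secreted and matrix proteins. Postn, which encodes the matrix protein periostin, fell by 6.21 ± 0.29 (log2 fold change, SE), from 5.55 ± 0.95 CPM to 0.0679 ± 0.0584 CPM. Prl2c3, a member of the prolactin family, had a log2 fold change of -4.98, the vitamin A transporter Stra6 of -4.65, the aldehyde dehydrogenase Aldh3a1 of -4.40, and Ibsp, encoding bone sialoprotein, of -3.83. Other large falls were those of the sodium-glucose cotransporter Slc5a9 at -5.27, Mab21l4 at -4.79, Asb2 at -4.69, Sparcl1 at -4.27 and the water channel Aqp1 at -3.77. Il33, which encodes an alarmin cytokine of the interleukin-1 family (chromosome 19, 29925113 to 29960718), fell from 42.7 ± 1.88 to 2.92 ± 0.32 CPM, a log2 fold change of -3.89 ± 0.08 with an edgeR adjusted p of 8.94e-13. The falling genes with the lowest p also held Cp, the copper-carrying ferroxidase ceruloplasmin (chromosome 3, 19956933 to 20009750), which fell from 1565 ± 51.7 to 237 ± 10.3 CPM, the integrin ligand Npnt at -1.85 and the focal adhesion protein Tns3 at -1.63.

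Most of the 12 largest rises were of genes known to be induced by interferon. Iigp1 rose by 3.69 ± 0.33 (log2 fold change, SE), from 1.60 ± 0.34 to 21.4 ± 7.17 CPM. The log2 fold change was 3.18 for Ifi44l, 3.11 for Oas2, 3.09 for Phf11b, 2.95 for Rsad2, 2.91 for Cmpk2, 2.84 for Usp18, 2.80 for Ifi44, 2.74 for Ifit3b, 2.64 for Trim30d and 2.60 for Ifit1bl2. Atf3, a stress-induced transcription factor, had a log2 fold change of 2.69 ± 0.51 and varied from 33.1 CPM in shTlr7 replicate 4 to 157 CPM in shTlr7 replicate 1. The rising genes with the lowest p were Larp1b, Pgap6, Tmem62 and Rogdi, with log2 fold changes of 1.27, 1.40, 1.59 and 1.44, and Ifi27, which rose from 88.0 ± 6.64 to 208 ± 12.4 CPM.

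Of 40 interferon-stimulated genes tested, 39 were higher and 0 lower, both over all genes and adjusted over the list alone, with a median log2 fold change of 1.78 (camera adjusted p = 5.09e-16). The list had an adjusted p = 0.367 with an estimated correlation, which came to 0.833 between its members. The RNA sensor Ifih1 rose from 38.0 ± 2.74 to 116 ± 14.3 CPM, the antiviral synthetase Oas1a from 9.13 ± 0.84 to 49.7 ± 8.44 CPM, Ifi35 from 44.7 ± 3.12 to 96.2 ± 6.01 CPM, and the RNA-editing enzyme Adar from 106 ± 7.07 to 179 ± 12.4 CPM. Gbp2, chosen after its values were seen, was the member not called, at 0.12 (edgeR adjusted p = 0.605). It passed the threshold without shCtrl replicate 4 (0.30, edgeR adjusted p = 0.0246), without both libraries numbered 4 (0.36, edgeR adjusted p = 0.00690) and with limma-voom (0.32, limma adjusted p = 0.00588).

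Around the targeted receptor, transcripts went both ways, and the list shares a member with the interferon-stimulated genes. Among 26 tested components of the TLR7 pathway, 11 were higher and 10 lower (11 and 11 adjusted over the list alone; camera adjusted p = 0.910). The transcription factor Irf5 rose from 9.07 ± 0.63 to 18.1 ± 1.01 CPM, the lysosomal nuclease Pld3 had a log2 fold change of 0.64, the adaptor Ticam1 of 0.61 and the kinase-binding protein Tab1 of -0.54. Larger changes were those of Irf7 at 2.60, Slc15a3 at -1.13 and Rab7b at -0.97, all chosen after their values were seen. Irf7 (edgeR adjusted p = 9.23e-06) is also a member of the list of interferon-stimulated genes. In MHC class I presentation, 9 of 13 tested members were higher and 2 lower (camera adjusted p = 0.0519, and adjusted p = 0.682 with an estimated correlation). B2m, the light chain of MHC class I, rose from 829 ± 20.5 to 1220 ± 147 CPM and Nlrc5, its transcriptional activator, had a log2 fold change of 0.91, while the chaperone Canx had one of -0.26. H2-T22 had a log2 fold change of 1.01 but has 2 further copies in the count table. Of the list's 23 genes, 13 have further copies in that table and 10 did not pass the filter on low counts. This list passed the threshold when shCtrl replicate 4 was left out (0.0359), when shTlr7 replicate 4 was left out (0.0250) and when copies were summed (0.0304).

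**Figure D2:**
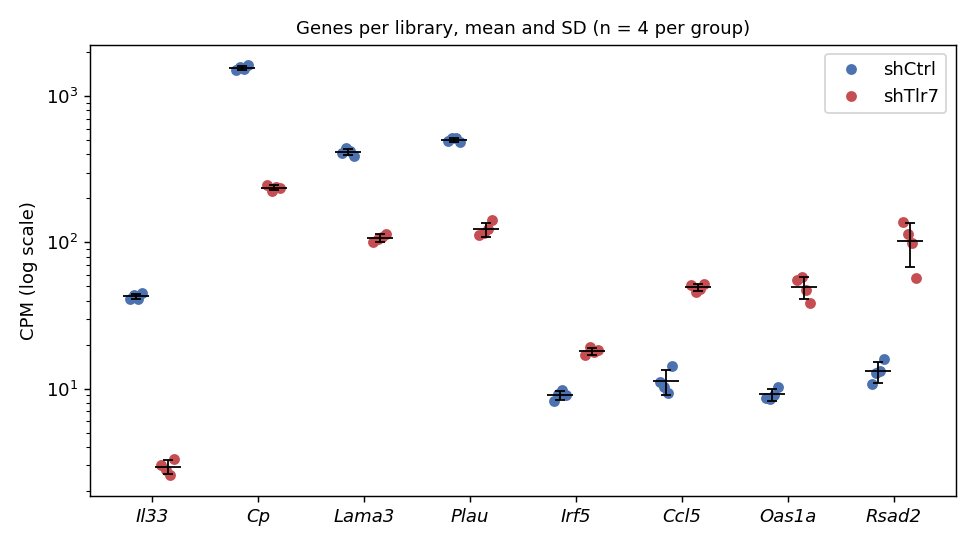
CPM of 8 genes in each library on a log axis, with group mean (horizontal mark) and SD (error bar, n = 4 per group). Il33, Cp, Lama3 and Plau are lower in all 4 shTlr7 libraries than in any shCtrl library, and Irf5, Ccl5, Oas1a and Rsad2 are higher.

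Transcripts of the extracellular matrix and of cell adhesion fell. Of 32 tested extracellular matrix genes, 27 were lower and 1 higher, with a median log2 fold change of -0.78 (camera adjusted p = 1.19e-09, and adjusted p = 0.0477 with an estimated correlation). The laminin chain Lama3 fell from 415 ± 21.6 to 107 ± 6.01 CPM, and the matrix protein Fbln2 from 971 ± 42.4 to 299 ± 20.3 CPM. Of 31 integrin and focal adhesion genes, 26 were lower and 1 higher, with a median of -0.29 (camera adjusted p = 2.23e-07, and adjusted p = 0.0477 with an estimated correlation). Among them were the collagen receptor subunit Itga2 at -1.06, the laminin receptor subunit Itga3 at -0.68, paxillin (Pxn) at -0.53 and the hyaluronan receptor Cd44 at -0.58. Of 19 mesenchymal genes, 17 were lower and 2 higher (camera adjusted p = 5.84e-06, and adjusted p = 0.0477 with an estimated correlation), including the tropomyosins Tpm1 at -0.82 and Tpm2 at -1.77. Twist2 also belonged to them, at -4.32 from a low level of 1.09 CPM, and 46.5% of its exons overlap another gene. The counts adjusted over each of these 3 lists alone were the same.

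The list of matrix remodelling enzymes holds proteases, their inhibitors and enzymes that modify or cross-link collagen, and the proteases were not tested alone. Of 37 tested matrix remodelling genes, 23 were lower and 6 higher (the same adjusted over the list alone), with a median log2 fold change of -0.55 (camera adjusted p = 3.88e-05, and adjusted p = 0.0754 with an estimated correlation). The urokinase gene Plau fell from 501 ± 14.2 to 123 ± 13.5 CPM, the membrane metalloprotease Mmp14 from 782 ± 15.7 to 354 ± 8.02 CPM, Adam8 from 167 ± 8.25 to 55.5 ± 3.94 CPM and the aggrecanase Adamts4 from 68.7 ± 2.08 to 16.3 ± 1.75 CPM. Mmp9 and Mmp13, 2 further metalloproteases chosen after their values were seen, had log2 fold changes of -2.97 and -3.23. None of the 6 higher genes is named here.

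Targets of several signalling pathways fell as well. Of 16 Wnt target genes, 13 were lower and 0 higher (camera adjusted p = 5.73e-05, and adjusted p = 0.0477 with an estimated correlation), among them the cyclin Ccnd1 at -0.75, Apcdd1 at -0.76 and the transcription factor Lef1 at -1.62. Of 25 TGF-beta target genes, 19 were lower and 4 higher (camera adjusted p = 6.62e-05, and adjusted p = 0.110 with an estimated correlation), including Ltbp2 at -2.09, Adam19 at -1.15, Pmepa1 at -0.93 and Skil at -0.52. Of 20 YAP and TEAD target genes, 12 were lower and 3 higher (camera adjusted p = 0.00292, and adjusted p = 0.0754 with an estimated correlation), including the nucleotidase Nt5e at -1.24, Amotl1 at -0.68, Ccn2 at -1.33 and Tgfb2 at -1.81. The counts adjusted over each of these 3 lists alone were the same.

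NF-kB target genes also fell, with exceptions. Of 33 tested, 21 were lower and 5 higher (the same adjusted over the list alone), with a median log2 fold change of -0.39 (camera adjusted p = 0.00173, and adjusted p = 0.658 with an estimated correlation). The inhibitor Tnfaip3 fell from 226 ± 22.7 to 94.1 ± 6.60 CPM, Nfkbiz from 134 ± 23.5 to 56.6 ± 2.12 CPM and the cytokine Il1b from 5.03 ± 0.73 to 1.07 ± 0.17 CPM. Il1a and Ptgs2, chosen after their values were seen, had log2 fold changes of -2.96 and -2.22. Among the 5 higher members, the chemokines Ccl2 and Ccl20, chosen in the same way, had log2 fold changes of 1.42 and 1.05. The chemokine Ccl5, which interferon signalling also induces, rose from 11.2 ± 2.15 to 49.3 ± 3.07 CPM.

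Of 39 axon guidance and neurotrophic genes, 24 were lower and 5 higher (the same adjusted over the list alone; camera adjusted p = 4.39e-04, and adjusted p = 0.0477 with an estimated correlation). The guidance cue Ntn1 had a log2 fold change of -1.10, the ephrin Efnb1 of -1.12 and the netrin receptor Unc5b of -0.70, whereas the semaphorin Sema3e rose by 1.40. Of 18 angiogenic factors, 8 were lower and 3 higher (the same adjusted over the list alone; camera adjusted p = 0.0395, and adjusted p = 0.142 with an estimated correlation), with the lymphangiogenic factor Vegfc at -1.43, Angptl2 at -0.75 and Pdgfc at -0.82. This list's camera adjusted p was 0.0542 without shTlr7 replicate 1, 0.0663 with a minimum of 1 CPM in 4 libraries and 0.0656 with thinned libraries. Of 46 ribosomal protein genes, 21 were lower and 5 higher (22 and 5 adjusted over the list alone; camera adjusted p = 0.0367, and adjusted p = 0.908 with an estimated correlation). Their median was -0.087, which became 0.016 under scaling by library size alone, and the list's adjusted p was 0.0627 without shCtrl replicate 1 and 0.105 without shTlr7 replicate 1. Rpl3 and Rpl24 had log2 fold changes of -0.32 and -0.26, and Rplp0 and Rplp1 of 0.29 and 0.30.

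**Figure D3:**
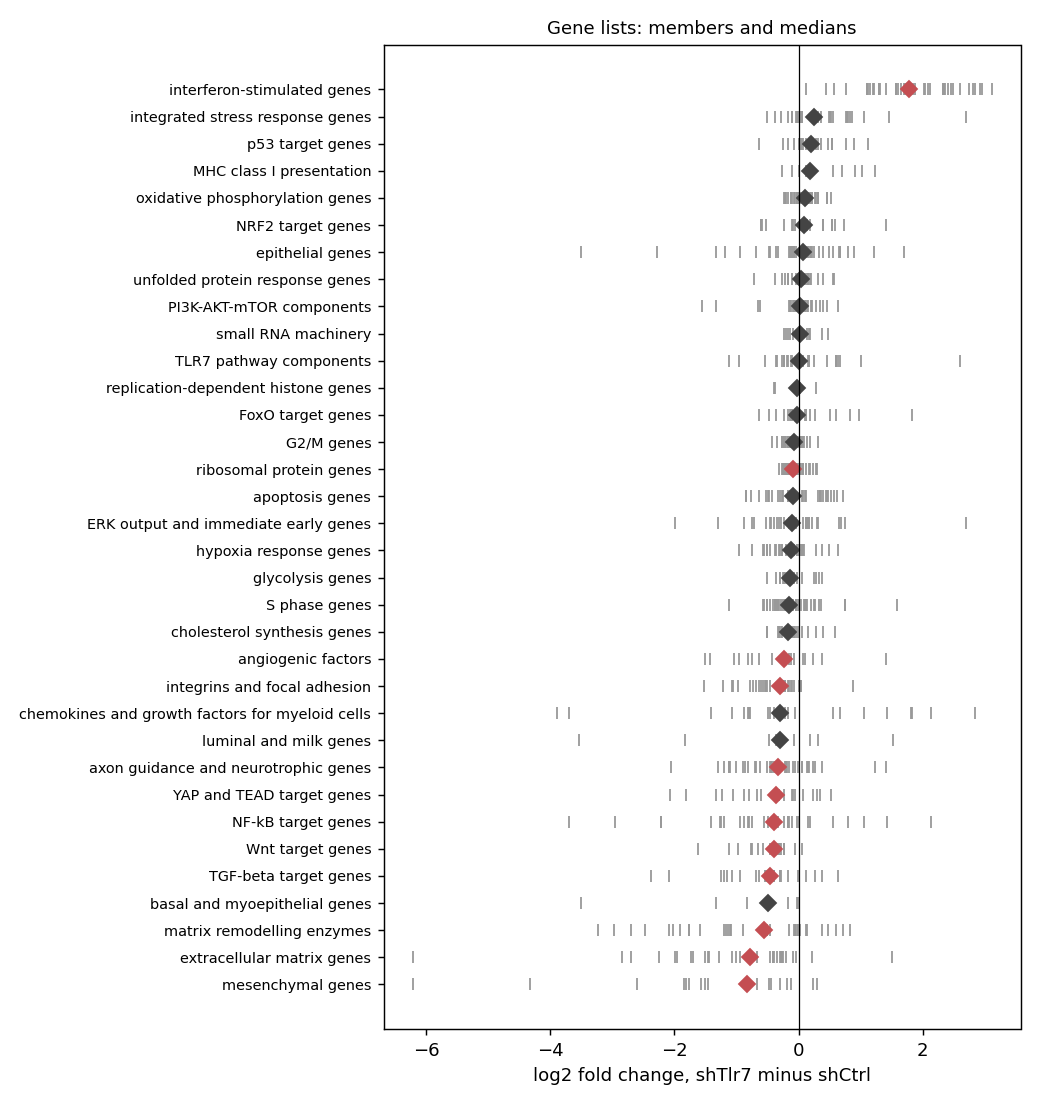
Log2 fold change (shTlr7 minus shCtrl) of the tested members of 34 gene lists (ticks) with each list's median (diamond). Red diamonds mark the 12 lists with a camera adjusted p under 0.05, of which 1 lies above 0 (interferon-stimulated genes, 1.78) and 11 below.

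Proliferation and metabolism lists did not pass the threshold. Of 40 G2/M genes, 3 were higher and 17 lower (camera adjusted p = 0.0717), and of 41 S phase genes, 8 were higher and 20 lower (0.113), with the cyclin Ccne1 at 1.59 and the repressor E2f8 at -1.12. Both lists passed without shCtrl replicate 4 (0.00551 and 0.0124), and the G2/M median of -0.08 became 0.03 under scaling by library size alone. The camera adjusted p was 0.0519 for hypoxia response genes (3 higher and 13 lower of 32; Vegfa at -0.96), 0.0519 for cholesterol synthesis genes (3 and 13 of 24; Srebf2 at -0.50), 0.137 for oxidative phosphorylation genes (17 and 5 of 42) and 0.155 for glycolysis genes (4 and 9 of 20). Leaving out 1 library brought hypoxia response genes past the threshold for shCtrl replicate 1 (0.0449) and shTlr7 replicate 2 (0.0110), and cholesterol synthesis genes for shCtrl replicate 4 (0.0411) and shTlr7 replicates 2 (0.0374) and 4 (0.0348).

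Stress and survival lists did not pass either. Of 23 p53 target genes, 10 were higher and 3 lower (camera adjusted p = 0.0512), with Cdkn1a at 1.12, which has a further copy in the count table, and Ccng1 at 0.54. The list was fixed as genes induced by p53, which 4T1 cells lack, so its changes cannot be read as p53 activity. This list passed without shCtrl replicate 4 (0.0379), shTlr7 replicate 2 (0.0374), shTlr7 replicate 3 (0.0491) or shTlr7 replicate 4 (0.0281), and with copies summed (0.0459). Of 30 integrated stress response genes, 15 were higher and 3 lower (0.0710, and 0.0157 without shTlr7 replicate 4), with Atf5 at 0.86 and Ddit3 at 0.80. The camera adjusted p was 0.431 for NRF2 target genes (8 higher and 5 lower of 23; Hmox1 at 1.40), 0.782 for apoptosis genes (12 and 16 of 34; Bcl2 at -0.85) and 0.821 for unfolded protein response genes (7 and 6 of 24; Edem1 at -0.72). Without both libraries numbered 4, the camera adjusted p passed the threshold for p53 target genes (0.0227), integrated stress response genes (0.0293), MHC class I presentation (0.0189), cholesterol synthesis genes (0.0293), G2/M genes (0.00911) and S phase genes (0.0200). Hypoxia response genes passed with thinned libraries (0.0423), and they and cholesterol synthesis genes passed after the GC and length correction (0.0416 for both). Over all tested genes 56.1% were called. Apoptosis genes held more called members than other genes, without a common direction (Fisher's exact adjusted p = 0.00925). Of the lists past the camera threshold, axon guidance and neurotrophic genes (0.0792), Wnt target genes (0.138) and YAP and TEAD target genes (0.250) did not pass Fisher's exact test. Angiogenic factors (0.922) and ribosomal protein genes did not pass it either, and the other lists past the camera threshold passed it.

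Among kinase pathway lists, 7 of 33 ERK output and immediate early genes were higher and 7 lower (camera adjusted p = 0.770). For PI3K-AKT-mTOR components the counts were 9 and 6 of 29 (0.910), with Irs1 at -1.55 and Inpp4b at -1.32. For FoxO target genes they were 6 and 5 of 22 (0.936), and for the small RNA machinery 5 and 2 of 14 (0.821), with Dicer1 at 0.18. Among lists not past the threshold, the counts adjusted over the list alone differed from those over all genes for S phase genes (9 higher and 20 lower), cholesterol synthesis genes (3 and 14), PI3K-AKT-mTOR components (8 and 6), epithelial genes and TLR7 pathway components. Scaling by library size alone turned the sign of the median for FoxO target genes (-0.03 to 0.07), apoptosis genes (-0.09 to 0.02) and histone genes (-0.02 to 0.09). The median and mean log2 fold change differed in sign for PI3K-AKT-mTOR components (0.03 and -0.06) and FoxO target genes (-0.03 and 0.13). Chemokines and growth factors for myeloid cells moved both ways, 7 higher and 10 lower of 22 (0.244), with Cx3cl1 at -0.78 and Cxcl11 at 1.83.

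Epithelial identity genes changed individually and in both directions. Of 40 epithelial genes, 16 were higher and 12 lower (18 and 12 adjusted over the list alone; camera adjusted p = 0.793), with a median log2 fold change of 0.07 and a mean of -0.06. The desmosomal protein Pkp1 fell from 34.7 ± 0.74 to 7.18 ± 0.56 CPM and the keratins Krt7 and Krt19 had log2 fold changes of -1.19 and -0.69, while the protease inhibitor Spint1 was at 0.80. Of 6 basal and myoepithelial genes tested, 4 were lower and 0 higher (camera adjusted p = 0.0519), and Krt14 fell from 36.2 ± 2.95 to 3.26 ± 1.08 CPM. The basal list passed without shCtrl replicate 4 (0.0411) or shTlr7 replicate 3 (0.0491). Of 10 luminal and milk genes, 2 were higher and 6 lower (0.0857), with lactoferrin (Ltf) at -3.53 and the casein Csn3 at 1.52.

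Most markers of other cell types were too low to test, and some of the tested ones were well expressed. Of 14 macrophage and leukocyte markers, 11 stayed under 1 CPM in every library. The 3 tested ones went both ways, with Cd14 falling from 65.4 ± 5.27 to 18.5 ± 3.24 CPM, Csf1r from 1.14 ± 0.20 to 0.241 ± 0.055 CPM, and Cd68 rising from 23.4 ± 2.36 to 38.5 ± 5.67 CPM. Of 12 fibroblast markers 3 were tested, and Fap rose from 0.359 ± 0.117 to 2.01 ± 0.39 CPM, while Pdgfra, at 42.3 ± 0.67 and 43.6 ± 2.13 CPM, had a log2 fold change of 0.04 and Col1a1, at 2.22 ± 0.70 and 1.64 ± 0.36 CPM, one of -0.41 (edgeR adjusted p = 0.504 and 0.124). Of 11 endothelial markers 2 were tested. Egfl7 rose from 13.3 ± 1.12 to 25.4 ± 0.95 CPM, and Flt1, at 101 ± 8.02 and 107 ± 6.65 CPM, had a log2 fold change of 0.07 (edgeR adjusted p = 0.321). Under scaling by library size alone, Pdgfra (0.14) and Flt1 (0.17) passed the threshold. So did Col1a1 with thinned libraries (-0.61) and with the replicate block (-0.38), and Flt1 (0.12) without both libraries numbered 4. Of 5 histone genes tested, 1 (H1f0) was higher and 1 lower (camera adjusted p = 0.910). No mitochondrially encoded transcript was in the count table. Exons of Irf5, Ifi35, Adar, H2-T22, Rogdi, Twist2, Adam19, Ccn2, Ccnd1, Lef1, E2f8, Irs1, Cxcl11, Rpl24, Csf1r and Egfl7 overlap those of another annotated gene by over 10% of their length, and their counts are uncertain to that extent, since the strand setting of the counting is not given.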

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

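The tests on GC content and transcript length, leukocyte RNA and the construct, and the fit without both libraries numbered 4, were chosen only after the result was seen. A library was singled out where its gap to the nearest other library, as a share of its group's range, exceeded Dixon's 95% critical value, which chance gives in about 1 in 20 groups. Of 254 groups of 4 values examined, 20 held such a library, where chance would give 12.7, and 17 of the 20 were libraries numbered 4 (14 in shCtrl and 3 in shTlr7).

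In shCtrl replicate 4, the second principal component was -12.4, and several transcripts stood above the other 3 shCtrl libraries. They were Adar at 116 CPM, Amotl1 at 1073 CPM, Gbp2 at 150.2 CPM, Lef1 at 2.65 CPM, Ltbp2 at 580.1 CPM, Ltf at 8.26 CPM, Nfkbiz at 169 CPM, Ptgs2 at 465 CPM, Slc5a9 at 28.9 CPM, Spint1 at 242 CPM and Tpm2 at 7.82 CPM. Angptl2 at 280.1 CPM and E2f8 at 209.8 CPM stood below the others in that library. In shTlr7 replicate 4, Aqp1 was low at 0.403 CPM, Ibsp was high at 1.18 CPM and the TMM factor was high at 1.05. Pgap6 was high at 30.1 CPM in shTlr7 replicate 1, Pmepa1 was high at 439 CPM in shCtrl replicate 1, and shCtrl replicate 2 had a high total of 51.5 M counts. Without both libraries numbered 4, 8259 genes passed the threshold, and the median log2 fold change of interferon-stimulated genes was 2.03.

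The difference between the groups covered 7517 of the 13393 genes tested. Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes, and the highest of the other splits gave 0 by the edgeR test. Each other split mixes the groups, so the group difference adds to the spread within its sides and a low count was likely in advance. The splits show that the count follows the grouping. They cannot show what 2 cultures with the same hairpin would give by chance. Depth could not account for the breadth, since 89.4% of the calls kept their direction and their side of the threshold with all libraries thinned to 18.1 M counts. A trend over GC content and transcript length could not account for it either, since 93.9% of the calls did so after that trend was removed. What stays open is whether the difference came from Tlr7 or from other differences between the 2 cell populations, which the design does not separate.

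Interferon-stimulated genes rose by a median of 1.78 on the log2 scale (camera adjusted p = 5.09e-16, and adjusted p = 0.367 with an estimated correlation). RNA from leukocytes is unlikely to be the source, since the median of 14 leukocyte markers in shTlr7 was 0.0171 CPM while the median rise of the list was 58.4 CPM. Depth is an unlikely cause too, since 97.8% of the list's median log2 fold change was left after thinning. A response to the hairpin construct and a response to less Tlr7 RNA cannot be told apart, because the ratio of Tlr7 counts of 0.475 has an interval that includes 1 and the series has 1 Tlr7 construct.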

How the results depend on the processing

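The alternatives that summed copies, thinned the libraries, left out both libraries numbered 4, or removed the GC and length trend were chosen after seeing the data. The number of called genes stayed within 1.5 times 7517 under all alternatives except a glmTreat fold of 1.5, which left 472 higher and 666 lower genes, 1138 in all, because it asks for a larger change. DESeq2 called 3629 higher and 3642 lower genes. Leaving out 1 library at a time gave 6705 to 7862 genes, of which 3476 to 4019 were higher and 3220 to 3843 lower. Of 3415 values of 171 named genes under the alternatives, 0 reversed, 5 no longer passed and 10 newly passed. Most of these genes were named for a large change or a low p in the same data, so few changes were likely in advance. Of all 7517 calls, 85.4% were kept with their direction under scaling by library size alone, and 88.0% without shTlr7 replicate 2. With the replicate block 99.6% were kept.

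Tlr7 had a log2 fold change of -1.49 under limma-voom, past the threshold, and the cause was not tested. With thinned libraries it was -1.86, the farthest from 0, and not past the threshold. Leaving out 1 library at a time gave -1.49 to -0.75. A minimum of 1 CPM in 4 libraries removed Tlr7 and gave no value. With 9 counts of Tlr7 in shCtrl and 7 in shTlr7, depth limits what can be said of it.

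Of the 34 lists tested, 12 passed with the preset correlation, 5 with an estimated correlation, which allows for members that vary together, and 20 with fry, which asks another question. Leaving out 1 library gave 10 lists (without shTlr7 replicate 1) to 18 lists (without shCtrl replicate 4). PI3K-AKT-mTOR components had the opposite direction with fry, at an adjusted p of 0.0420, and the cause was not tested. As many lists were past the threshold in 18 of the 35 splits, with up to 17 in a split other than the real one. Of 16 splits that part the shCtrl libraries 3 against 1, which keep part of the real difference, 14 gave as many. Of 18 that part them 2 against 2, 3 gave as many, with up to 13, so chance cannot be excluded for the number of lists. By the mean difference of each list, only the real split was as large for 11 of the 12 lists and for 8 of the 22 not past the threshold (exact permutation p = 0.0286, the smallest 35 splits can give, and 0.0511 after Benjamini-Hochberg adjustment over 34 lists). The first principal component held 74.5% of the variance over all tested genes, and 85.6% over the 1000 most variable.

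The replicate numbers were not taken to pair the libraries, because the labels do not tie them and the correlations of deviations between libraries with the same number were -0.00676, 0.114, 0.118 and 0.380. The 0.380 was that of the libraries numbered 4, and not every library correlated best with its own number. With the replicate block, 8339 genes (4334 higher and 4005 lower) passed, and Tlr7 was at -1.08. With the block 15 lists passed, with p53 target genes (camera adjusted p = 0.0410), hypoxia response genes (0.0426) and integrated stress response genes (0.0426) newly past the threshold.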

Other observations

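The interferon transcripts, the comparison of sites and the tests on base composition and on the guide's seed were chosen only after the result was seen. Interferon transcripts were few. Ifnb1, which encodes interferon beta, had 2, 0, 1 and 2 counts in shCtrl replicates 1 to 4 and 3, 13, 8 and 0 in shTlr7 replicates 1 to 4. The ratio of the pooled counts was 2.93 with an exact 95% interval from 1.10 to 9.84 (exact binomial test, two-sided p = 0.0215, and 0.0429 adjusted over 4 interferon transcripts). It was 1.62 without shCtrl replicate 2, with an interval from 0.605 to 5.43 (exact p = 0.397), and 2.43 without shTlr7 replicate 3 (exact p = 0.0812), so this difference rests on single libraries. Ifnl2, which encodes an interferon lambda, had no counts in shCtrl and 2, 7, 4 and 1 counts in shTlr7 replicates 1 to 4, for which the exact 95% interval of the ratio lies above 2.03 (exact binomial test, two-sided p = 0.00160, adjusted 0.00641), and above 1.12 without shCtrl replicate 2. Ifna4 (1 and 4 counts) and Ifnl3 (1 and 5 counts) did not pass (exact binomial test, two-sided p = 0.656 and 0.419, adjusted 0.656 and 0.558). These tests cover counting error only, not the spread between libraries.

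A word search of 3′ UTRs asked whether lower transcripts share a short sequence, as transcripts hit by the seed of a hairpin's guide strand would. Of 16182 words of 7 bases in 9967 genes, GCCGGTG lay farthest from 0 (z = -6.36, 358 genes), where 200 random reassignments of the fold changes reached at most 5.25, and the other words of the same bases reached -3.32 at the lowest. AGCCGGT (z = -5.76) and TGCCGGT (z = -5.33) also went beyond 5.25. Log2 fold changes were limited to 2 either way and adjusted for length and GC content of the UTR and of the whole transcript. Their mean was then -0.30 ± 0.06 (SE) for the 78 genes with GCCGGTGA and -0.10 ± 0.02 for 280 with GCCGGTG without the A. It was -0.047 ± 0.034 for 118 other genes with CCGGTGA and -0.032 ± 0.018 for 583 with CCGGTG alone. For 8908 genes with none of these sites in the 3′ UTR it was 0.0084 ± 0.0045. The part before the 3′ UTR could be searched for 6963 of the 9967 genes. Among those with none of these sites in the 3′ UTR, 143 genes with GCCGGTGA before it had a mean of -0.12 ± 0.04. The Tlr7 transcripts hold GCCGGTGA once, in the coding sequence of the last exon (chromosome X, 167306570 to 167306577, minus strand, GRCm38). Of 3525 transcripts of similar length, 3.01% hold GCCGGTGA, and 13.2% hold GCCGGTG, the word that the search found. A seed match of the hairpin's guide may lower some of the transcripts with this site, a hypothesis found and tested on the same data. The hairpin's sequence is not given in the sources used here. Of 2826 lower genes searched, 160 (5.66%) carry the word, against 3.59% of all genes searched, and effects that pass through other genes were not tested.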
